A study of Bos taurus with 24 samples.

How the data were processed

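Muscle RNA from 12 cows, 6 per gain class, was measured at 2 biopsies per cow on 24 Affymetrix arrays. Per the labels' protocols, total RNA was extracted with TriPure Reagent, and biotin-labelled cRNA was made from it by the standard Affymetrix protocol. Affymetrix Expression Console and Transcriptome Analysis Console were used, per the submitters' processing notes; their versions and the normalization method are not given in the sources used here. The values were deposited as a single table on a log scale, taken as log2 from their range, since the base is not stated.

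The columns differed by biopsy. The highest value was 19.8071 among biopsy 1 arrays and 19.9315 among biopsy 2 arrays, and upper quartiles were 9.17 to 9.34 and 9.34 to 9.44, so the 2 sets appeared to have been normalized separately. The plan called for a further normalization where distributions differed, so comparisons between biopsies used quantile normalization over all 24 arrays, which removes a difference of distribution but no shift of single genes. Comparisons of gain classes used the values as deposited. A feature within 0.05 of its set's highest value was called saturated: 1 gene was saturated on all 24 arrays, 22 on every array of at least 1 group and 43 on at least 1 array.

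Of 26773 features 18790 were paired with 1 gene by the platform annotation, 385 with several and 7598 with none. Symbols were checked through the Entrez number, found for 18003 features, and none changed. For the 320 genes with more than 1 feature the feature with the highest mean was kept. Genes with a mean under the 25th percentile of all features (6.76) were left out, which left 14198 of 18444.

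Tests were made with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend), with Benjamini-Hochberg adjustment and a threshold of 0.05. The change between biopsies was fitted with each cow as a fixed block, separately in each gain class and then averaged, and the interaction was the difference of the 2 changes. Both classes were in the same fit and shared its estimate of each gene's spread. The SE, p and count of a class therefore also depend on the cows of the other class. The block was used because the titles carry the same animal number on both biopsies. The correlation of a cow's 2 arrays, as deviations from their group means, was -0.206 to 0.349, with a median of 0.160 against 0.030 for different cows, and 5 of 12 cows were best matched by their own other biopsy. Gain classes were compared within each biopsy, 6 cows against 6, and on each cow's mean over both biopsies. Standard errors are limma's moderated values.

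Before the data were examined, 27 gene lists were fixed, 20 of pathways and 7 of cell type markers, together with the tests, the naming rule and the alternatives. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, and with an estimated correlation and fry as alternatives. The naming rule took, among genes past the threshold, the 8 largest increases and the 8 largest decreases that went the same way in at least 10 of 12 cows, or 5 of 6 within a class. Comparisons of gain had no such condition. Where fewer than 5 genes passed in a direction, it took the 5 with the smallest p. Symbols that begin with LOC, or are only an accession, clone or open reading frame name, were passed over. Rankings by size or p below hold among the other symbols. From each list it added the 4 members with the smallest p and any other that passed. Fibroblast markers shared 5 genes with the extracellular matrix list, adipocyte markers shared none with the synthesis list, and several adipocyte markers, LPL, PNPLA2 and GPD1 among them, are also expressed in muscle fibres. The text gives a part of the genes so named, and says where a gene was chosen after its values were seen.

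The functions were tested on simulated data for 14198 genes with the means and spreads of the real genes, independent of each other, and 200 changed genes. For a change of 1 on the log2 scale the recovered share was 88.1% between biopsies in all cows, 44.8% for the interaction, 61.2% for gain at biopsy 1, 62.7% for gain at biopsy 2 and 77.6% for gain over both biopsies. For a change of 0.5 these were 52.2%, 2.99%, 19.4%, 25.4% and 44.8%.

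Odorant receptor genes were taken by symbol, after the separate sets were seen, as a measure of change between sets in genes that muscle is not known to need. Alternatives covered median centring, cyclic loess, the filter on dim genes, the features of a gene, the moderation, array weights, the block and leaving out each cow. Added after seeing the data were the values as deposited, a limit of size from odorant receptor genes, leaving out the 2 cows with an array apart, and adipocyte markers as a covariate. Probe sequences, a genome and scanner files were not used here, so GC content was not tested and no coordinates are given.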

Results

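Gluteus medius muscle, a hindquarter muscle, was sampled by needle biopsy from 12 crossbred beef cows. The cows were the 6 highest and 6 lowest gaining animals of 121 in a feeding trial, and gain was measured while feed was offered freely. Each cow was sampled on 2 occasions. The protocol describes a biopsy on day 105 of a 112-day period on a diet of 120 kcal of metabolizable energy per kg of metabolic weight, and a biopsy on day 49 of a later 112-day period of free access to feed. The labels number the biopsies 1 and 2 without naming the period, and the numbers are read here in the protocol's order, restriction first. The 24 arrays fell into 4 groups of 6: high gain at biopsy 1, high gain at biopsy 2, low gain at biopsy 1 and low gain at biopsy 2. The stated aim was to find muscle transcripts that differ with body weight gain after restriction and after free feeding.

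The deposited table held log2 values for 26773 array features, and 14198 named genes were tested. Median values were 7.68 to 7.88 on the biopsy 1 arrays and 7.79 to 7.85 on the biopsy 2 arrays. The highest value was 19.81 on biopsy 1 arrays and 19.93 on biopsy 2 arrays, so the 2 sets appeared to have been normalized separately. Biopsy number and processing set therefore cannot be told apart in any comparison between biopsies, whereas comparisons of gain classes within a biopsy lie inside 1 set. Between 46 and 65 features per array lay at the upper limit of the scale, where only a lower bound is measured, among them the muscle transcripts TTN on all 24 arrays and ACTA1 and MYH7 on most. The number of arrays limits the precision of every value below.

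Array 4 of the low gain cows at biopsy 1 stood apart in its tissue markers. ACTA1, skeletal muscle actin, read 14.5 on it and at least 19.7 on the other 11 biopsy 1 arrays, and the creatine kinase gene CKM read 14.6. On the same array ADIPOQ, the adipocyte hormone adiponectin, read 18.0 and the connective tissue proteoglycan DCN read 17.7. The array's median correlation with its group was 0.862. Array 4 of the high gain cows at biopsy 2 had a median correlation of 0.942, with ADIPOQ at 18.2 and the fatty acid synthase FASN at 19.0. ACTA1 was at the upper limit, where a loss of muscle signal need not show. CKM read 19.2 and MYH7 19.5 on it, below the set's upper limit of 19.93. These genes were chosen after their values were seen.

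**Figure D1:**
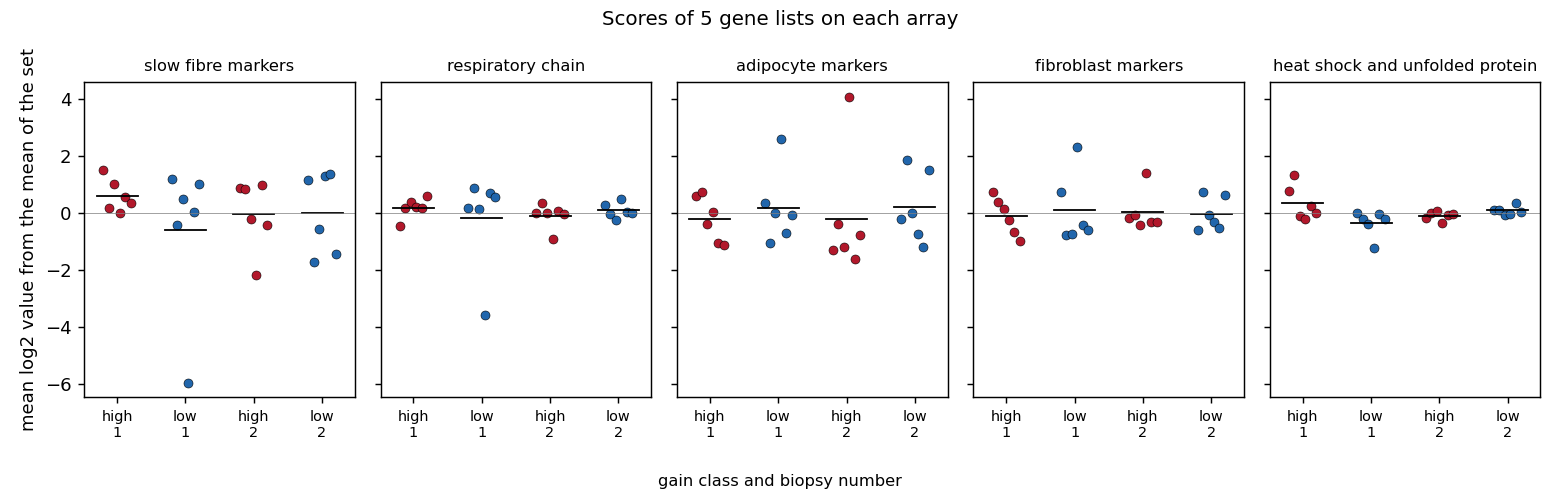
Mean log2 value of 5 gene lists on each array, as the distance from the mean of the 12 arrays of the same biopsy, for 6 cows per group; points are arrays and black lines are group means. Low gain array 4 at biopsy 1 lies at -5.96 for slow fibre markers and 2.60 for adipocyte markers, and high gain array 4 at biopsy 2 lies at 4.08 for adipocyte markers.

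The comparison of biopsies asked what changed within cows between the feeding periods. THRSP, a lipogenic regulator responsive to thyroid hormone, was 3.66 ± 1.15 higher on the log2 scale (SE, n = 12 cows), and ACSS2, which makes acetyl-CoA from acetate, 2.76 ± 0.73, each in 11 of 12 cows. PCK2, the mitochondrial phosphoenolpyruvate carboxykinase, rose by 2.60 ± 0.83, the small heat shock protein gene HSPB7 by 2.43 ± 0.67, AGPAT2, an acyltransferase of triglyceride synthesis, by 2.38 ± 0.64, SHISA4 by 2.36 ± 0.31, the mitochondrial carrier gene SLC25A39 by 2.11 ± 0.17 and ENTREP1 by 2.04 ± 0.27. The largest decreases were in FABP2, a fatty acid binding protein (-2.38 ± 0.47), the co-chaperone gene DNAJB4 (-1.94 ± 0.34), the myogenic regulator MYOG (-1.81 ± 0.27), RSRC2 (-1.75 ± 0.22) and the homeobox gene MEOX2 (-1.71 ± 0.43). DDX5, an RNA helicase (-1.65 ± 0.30), CCNL1, a cyclin linked to splicing (-1.65 ± 0.16), and PNISR (-1.63 ± 0.20) followed. On the array THRSP was feature 12833855, ACSS2 12714225, SLC25A39 12769217, MYOG 12738482 and CCNL1 12680419. ACSS2 averaged 9.50 ± 0.52 (SD, n = 6) in high gain cows at biopsy 1 and 12.60 ± 2.95 at biopsy 2, and 10.85 ± 1.88 and 13.26 ± 1.60 in low gain cows.

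Of 14198 genes, 5414 (38.1%) changed between biopsies on average over the 12 cows, by limma at an adjusted p under 0.05. Of the 5414, 2949 rose and 2465 fell. Counts of list members past the threshold, given below, are to be read against the share of 38.1%. Odorant receptor genes, which encode smell receptors, served as a control for change between the processing sets. Without a filter on dim genes 375 of 806 of them passed (46.5%), against 41.8% of the other 17638 genes. The 99th percentile of the odorant receptor genes' absolute change was 1.03, and 369 tested genes passed with a larger change, 284 upward and 85 downward. Most odorant receptor genes were dim, with a median level of 6.36 and 272 of 806 above the limit of 6.76. The value of 1.03 therefore need not bound a processing shift in brighter genes. With the values as deposited the share of calls that were higher at biopsy 2 was 70.8% in place of 54.5%, and the median of all genes moved from 0.02 to 0.12.

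**Figure D2:**
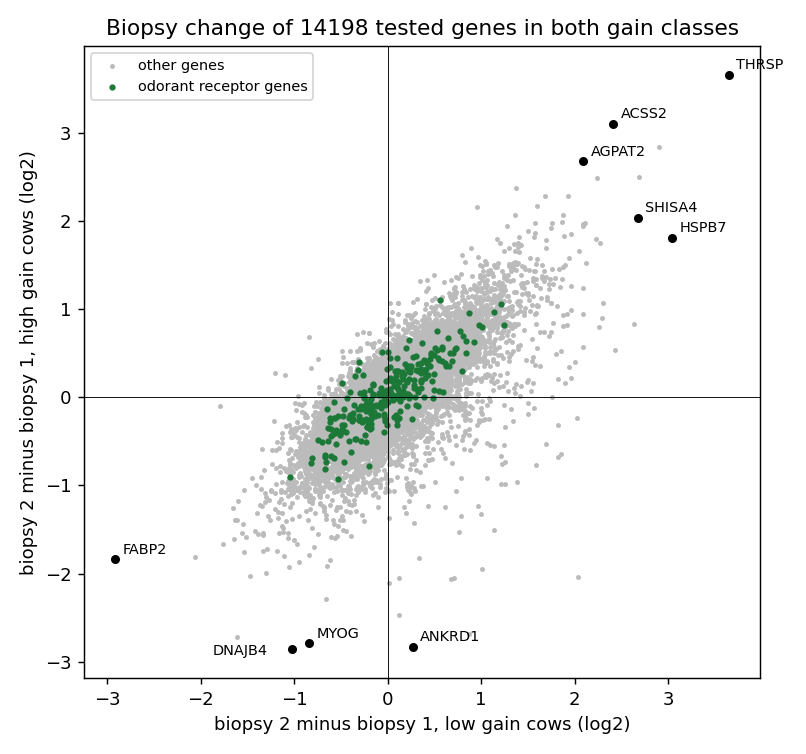
Log2 change from biopsy 1 to biopsy 2 of each of 14198 tested genes in low gain cows (x axis, 6 cows) and high gain cows (y axis, 6 cows); green points are odorant receptor genes and black points are named examples. The changes of the 2 classes correlate at 0.766 across genes, and odorant receptor genes lie along the same diagonal.

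Fatty acid and triglyceride synthesis was the only fixed list of 27 whose shift between biopsies passed limma's camera with the preset correlation (adjusted p = 0.0113, median log2 change 1.48). With an estimated correlation the adjusted p was 0.995, and by limma's fry, which asks whether a list moves on balance in a direction, it was 0.0611. Of its 21 tested members 8 rose and none fell, or 10 and none when adjusted over the list alone. Besides THRSP, ACSS2 and AGPAT2, these were the carbohydrate response factor MLXIPL (1.04 ± 0.14), the sterol and lipid regulator SREBF1 (0.61 ± 0.11), malic enzyme ME1 (1.25 ± 0.30), the citrate carrier SLC25A1 (1.61 ± 0.57) and the acyltransferase DGAT1 (0.43 ± 0.14). FASN (2.36 ± 1.06) and the desaturase SCD (1.48 ± 0.56, at the upper limit on 4 arrays), chosen after their values were seen, did not pass, with limma adjusted p of 0.0953 and 0.0523. SCD passed under 10 and FASN under 4 of the alternative settings. Without the 2 cows with an array apart the list's median was 1.36, and 18 members rose and 1 fell. The medians moved apart in the classes, from 1.46 to 0.52 in high gain and from 1.47 to 2.30 in low gain cows. The difference of the classes moved from 0.03 to -1.45, which passed camera with the preset correlation (adjusted p = 2.21e-06), and the adjusted p was 0.457 with an estimated correlation. The same difference moved to -0.98 in adipocyte markers (adjusted p = 1.56e-06) and to -0.84 in extracellular matrix genes (adjusted p = 1.24e-07), again 0.457 with an estimated correlation. The 2 cows were left out after their values were seen, and they had the list's largest rise and largest fall. Leaving them out moves the classes apart in this direction, so these p values do not test a class difference. The change varied with the adipocyte markers: the list rose by 5.48 in high gain cow 4, whose adipocyte markers rose by 4.48, and fell by 1.88 in low gain cow 4, whose adipocyte markers fell by 3.06.

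Of 16 adipocyte markers 3 rose and none fell between biopsies (2 and none adjusted over the list alone, 4 and none without the 2 cows with an array apart): the glycerol channel AQP7 (1.97 ± 0.39), the lipase PNPLA2 (1.32 ± 0.32) and lipoprotein lipase LPL (1.25 ± 0.43), all of which muscle also uses. ADIPOQ (-0.68 ± 1.08), the lipid droplet protein PLIN1 (-0.34 ± 0.90) and FABP4 (-1.10 ± 1.27), chosen after their values were seen, did not pass. Without low gain cow 4 ADIPOQ and PLIN1 were 0.075 and 0.26 and FABP4 was -0.33. FABP4 was -0.56 without high gain cow 1, -1.77 without high gain cow 4 and -1.96 without low gain cow 2.

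**Figure D3:**
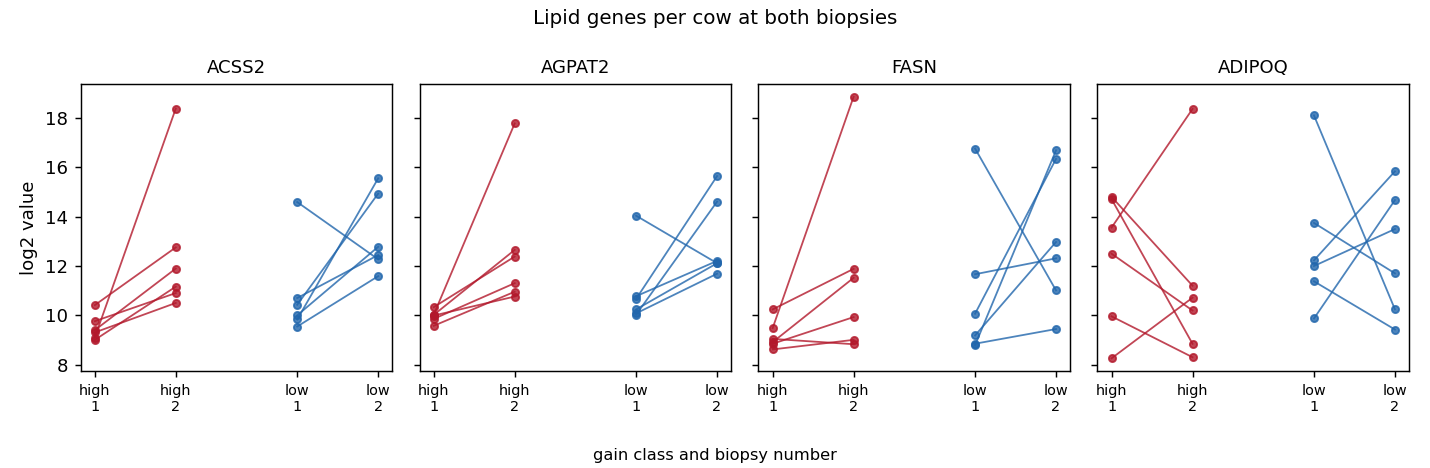
Log2 values of ACSS2, AGPAT2, FASN and ADIPOQ at biopsy 1 and biopsy 2 after quantile normalization over all arrays; each line is 1 cow, 6 high gain (red) and 6 low gain (blue). ACSS2 and AGPAT2 are higher at biopsy 2 in 11 of 12 cows, FASN in 10 and ADIPOQ in 5.

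**Figure D4:**
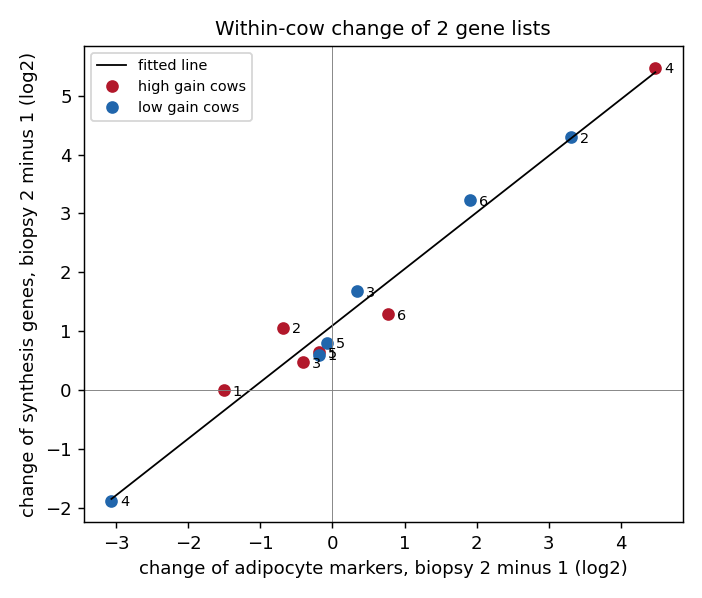
Mean log2 change from biopsy 1 to biopsy 2 of the fatty acid and triglyceride synthesis list (y axis) against that of the adipocyte markers (x axis) in each cow, 6 high gain (red) and 6 low gain (blue), numbered by replicate, with the fitted line. The line crosses no change of adipocyte markers at 1.09, and the synthesis list lies above the adipocyte markers in 12 of 12 cows.

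Of 16 sterol synthesis genes 8 rose and none fell, or 10 and none adjusted over the list alone. They included INSIG1, a sterol sensor (1.39 ± 0.33), the isomerase IDI1 (1.26 ± 0.36), squalene synthase FDFT1 (1.04 ± 0.22) and the regulator SREBF2 (0.52 ± 0.10), but the list did not pass camera (adjusted p = 0.0861). Of 26 fatty acid oxidation genes 6 rose and none fell, among them ACADS (1.86 ± 0.31), ECHS1 (1.28 ± 0.28) and CPT2 (1.08 ± 0.22), enzymes of mitochondrial beta-oxidation. Of 35 respiratory chain genes 6 rose, including the nuclear receptor ESRRA (1.34 ± 0.16) and COX5B (1.57 ± 0.47), and 2 fell. In glycolysis and glycogen metabolism 2 of 20 genes rose and 2 fell: the glucose transporter SLC2A4 was 1.46 ± 0.48 and the glycogen branching enzyme GBE1 0.72 ± 0.26, against hexokinase HK2 at -0.85 ± 0.21 and lactate dehydrogenase LDHA at -1.31 ± 0.41 (-0.73 when its features were averaged). None of 19 citric acid cycle, 14 slow fibre or 13 fast fibre genes passed. Without the 2 cows with an array apart the counts up and down were 9 and 1 for sterol synthesis, 5 and 1 for oxidation, 13 and 6 for respiratory chain, 2 and 7 for glycolysis, 4 and 4 for citric acid cycle, 0 and 0 for slow fibre and 1 and 1 for fast fibre genes. The glycolysis median was then -0.28 in place of -0.01. Adjusted over the list alone, 5 oxidation genes rose, 4 respiratory chain genes rose and 2 fell, and 1 glycolysis gene fell. None of these lists passed camera. Among all 14198 tested genes 38.1% passed, so a count of members past the threshold does not by itself set a list apart.

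In growth and protein turnover, 9 of 26 IGF, insulin and mTOR genes rose and 3 fell, including the growth hormone receptor GHR (0.95 ± 0.17) and the cap-binding factor EIF4E (-1.24 ± 0.17). Of 25 atrophy and autophagy genes 8 rose, such as the kinase ULK1 (0.59 ± 0.10) and the glucocorticoid target KLF15 (0.46 ± 0.08), and 3 fell. The proteasome had 5 of 31 genes up and 4 down, the myogenic list 4 of 18 up and 5 down, and the cell cycle 5 of 17 up and 4 down. Of 22 antioxidant and metallothionein genes 6 rose and none fell, with GPX1 (1.46 ± 0.25), NQO1 (1.11 ± 0.18) and MT3 (0.95 ± 0.10); fry gave an adjusted p of 0.0316, and camera 0.172. Adjusted over the list alone the proteasome had 2 up and 4 down, and the counts of the other 5 lists were unchanged. Leaving out the 2 cows with an array apart gave 9 up and 6 down for IGF, insulin and mTOR, 7 and 4 for atrophy, 6 and 8 for the proteasome, 4 and 5 for myogenic, 5 and 3 for cell cycle and 7 and 1 for antioxidant genes. Changes under 1.03 in size lay within the range of 99% of odorant receptor genes. The share of all tested genes past the threshold was 38.1%.

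Among 16 clock genes 4 rose and 1 fell, with NR1D1 (1.34 ± 0.24) and DBP (0.86 ± 0.13) higher and CRY1 (-0.50 ± 0.12) lower. Of 15 glucocorticoid-responsive genes 2 rose and 1 fell, or 1 and 1 adjusted over the list alone, which left the counts of the other 4 lists here unchanged. Of 17 interferon-stimulated genes 2 rose and 4 fell, including the antiviral genes MX1 (-1.02 ± 0.18) and RSAD2 (-0.65 ± 0.15). Of 18 immediate early genes 2 rose, including JUNB (0.99 ± 0.16), and of 19 heat shock genes 2 rose, HSPB1 (1.40 ± 0.19) and CRYAB (1.49 ± 0.41, at the upper limit on 2 arrays), and 4 fell, including the stress factor DDIT3 (-0.67 ± 0.11). With the 2 cows with an array apart left out, 6 clock genes rose and 1 fell, with 3 and 2 for glucocorticoid-responsive, 4 and 4 for interferon-stimulated, 3 and 0 for immediate early and 3 and 5 for heat shock genes. Median, mean and camera direction differed in sign for the myogenic, interferon, heat shock and Schwann cell lists, none of which passed camera.

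Among markers of other cell types, none of 16 fibroblast or 11 smooth muscle and pericyte markers passed, and 1 of 38 extracellular matrix genes fell. Of 20 macrophage and leukocyte markers 5 rose and 4 fell, with C1QA at 1.04 ± 0.20 and CD53 at -0.90 ± 0.12. Of 17 endothelial markers 4 rose and 1 fell, of 10 red blood cell markers 2 rose, and of 8 Schwann cell and nerve markers 3 rose and 1 fell. Adjusted over the list alone, no matrix gene fell, 3 endothelial markers rose and 1 fell, no red blood cell marker rose, and 3 Schwann cell markers rose and 2 fell. When the 2 cows with an array apart were left out, the counts up and down were 1 and 0 for fibroblast, 2 and 0 for smooth muscle, 4 and 1 for matrix, 4 and 4 for macrophage, 5 and 2 for endothelial, 1 and 1 for red blood cell and 3 and 2 for Schwann cell genes.

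Within high gain cows the increases named by the rule included ACSS2 (3.10 ± 1.04, SE, n = 6), the glutathione transferase GSTM2 (2.28 ± 0.20), AQP7 (2.07 ± 0.54) and the lipogenic cofactor MID1IP1 (1.99 ± 0.41). The decreases included DNAJB4 (-2.86 ± 0.48), the stretch-responsive gene ANKRD1 (-2.83 ± 0.66), MYOG (-2.79 ± 0.38), the kinase ROCK2 (-2.11 ± 0.41) and NEXN (-2.05 ± 0.48). ACSS2 passed narrowly (adjusted p = 0.0499) and lost its call when any of 10 cows was left out singly, with 1.87 without high gain cow 4 and up to 3.50 without the others. Low gain cows were among the 10, since both classes share the fit and its estimate of spread. In all, 2876 genes changed, 1636 upward and 1240 downward by limma. The count was 1753 without high gain cow 1 and 1899 without high gain cow 2.

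Within low gain cows HSPB7 (3.05 ± 0.95, SE, n = 6), SHISA4 (2.68 ± 0.44), the chaperone CRYAB (2.44 ± 0.59), the actin-associated SYNPO (2.23 ± 0.41) and the ketone body enzyme BDH1 (2.09 ± 0.68) were among the largest increases. Without low gain cow 4, whose biopsy 1 array had little muscle signal, CRYAB was 1.58 and still passed. HSPB7 (2.10, limma adjusted p = 0.0943) and BDH1 (1.49, limma adjusted p = 0.118) lost their calls without that cow, as they did without some other cows. FABP2 (-2.92 ± 0.66), PNISR (-1.64 ± 0.28), HNRNPA1 (-1.61 ± 0.29) and SRSF5 (-1.54 ± 0.35), the last 2 encoding splicing proteins, were among the largest decreases. In all, 2878 genes changed, 1535 upward and 1343 downward. Of the 2876 genes called in high gain cows 97.8% had the same sign in low gain cows, and 1791 genes were called in both classes with the same sign, where independent lists would share 294.2. Across genes, which are not independent replicates, the changes of the 2 classes had a Pearson correlation of 0.766 and a Spearman correlation of 0.773. Both classes share the processing sets, which can add to the correlation and to the overlap of calls. They also share the estimate of each gene's spread, which can add to the overlap, so 294.2 is a low baseline.

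The interaction asked whether the change between biopsies depended on gain class, and a fixed shift between sets cancels in it. The smallest unadjusted p values were in NMRK1, a nicotinamide riboside kinase whose change was 0.79 ± 0.17 greater in high gain cows, and LYPD3 (0.54 ± 0.13), and on the other side in ZBTB2 (-0.58 ± 0.13), SPEN (-1.08 ± 0.25), NUP88 (-0.80 ± 0.18) and ROCK2 (-2.12 ± 0.58). Among fixed lists of muscle repair and stress genes, ANKRD1 was -3.10 ± 0.94, XIRP1 -2.95 ± 1.04, MYOG -1.95 ± 0.54, the immediate early genes FOS -2.49 ± 0.98, ATF3 -2.36 ± 0.93 (-1.55 without high gain cow 2) and FOSB -1.59 ± 0.50, and the heat shock genes HSPH1 -2.19 ± 0.72 and HSPA8 -1.08 ± 0.35. The growth inhibitor MSTN was 1.52 ± 0.45 and the clock gene PER3 0.88 ± 0.25. None passed: by limma 0 of 14198 genes had an adjusted p under 0.05 (smallest 0.9996), and 512 had an unadjusted p under 0.05 where chance gives 709.9.

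By camera with the preset correlation 6 lists had a lower shift in high gain cows: heat shock (median -0.69), immediate early (-0.56), myogenic (-0.40), slow fibre (-1.10), citric acid cycle (-0.57) and respiratory chain (-0.50). None passed with an estimated correlation, where the adjusted p was 0.326 for heat shock, 0.479 for immediate early, 0.937 for myogenic and 0.962 for the other 3. Without the 2 cows with an array apart, the medians of slow fibre, citric acid cycle and respiratory chain turned to 0.34, 0.39 and 0.42, while heat shock was -0.72 and immediate early -0.49; myogenic was -0.14 and lost its call (adjusted p = 0.154). With the preset correlation 14 lists then passed camera. Citric acid cycle, respiratory chain, atrophy (0.23), proteasome (0.20) and fast fibre (0.18) passed as higher in high gain cows. Fatty acid synthesis, adipocyte, matrix, fibroblast (-0.50), endothelial (-0.35), smooth muscle (-0.34) and macrophage genes (-0.15) passed as lower, as did heat shock and immediate early. No list passed with an estimated correlation, where the smallest adjusted p was 0.457. Which cows to leave out was decided after their scores were seen, so the calls without them do not test a class difference. Adjusted over the list alone 2 myogenic genes passed as lower and none in the other 5 lists. The count of lists was 10 without low gain cow 4 and 10 without low gain cow 6. High gain cows were uneven at biopsy 1. Heat shock scores there were 0.76 and 1.35 in cows 1 and 2 and -0.20 to 0.24 in the other high gain cows. Immediate early scores were 1.06 and 1.34 in cows 2 and 5 and -0.70 to -0.14 in the other high gain cows.

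At biopsy 1 the question was which transcripts differed with gain class late in restriction. MYOG averaged 12.61 ± 0.60 (SD, n = 6) in high gain and 10.58 ± 1.48 in low gain cows, a difference of 2.03 ± 0.58 (SE). Low gain array 4, with little ACTA1, read 7.62 for MYOG, and the other low gain arrays read 10.89 to 11.65. That array lowers the low gain mean and widens its SD, and with array weights the MYOG difference was 1.33. The myogenic factor MYOD1 differed by 0.90 ± 0.27, ANKRD1 by 2.57 ± 1.01 (1.57 without low gain cow 4) and XIRP1 by 2.31 ± 1.01 (1.38 without high gain cow 2). Among genes the naming rule allows, the smallest unadjusted p values on the side higher in high gain cows included FAM118B (0.64 ± 0.13) and the riboflavin kinase RFK (0.45 ± 0.11). The transcriptional repressor SPEN (1.16 ± 0.28) and DDIT3 (0.64 ± 0.15) were also among them. LYPD3 (-0.47 ± 0.10), RAB7B (-0.64 ± 0.15) and TCP11L2 (-0.71 ± 0.16) were lower, as were the clock genes NR1D1 (-0.89 ± 0.33) and DBP (-0.61 ± 0.24, and -0.40 without low gain cow 4) and the fast fibre calcium buffer PVALB (-1.09 ± 0.39). The stress genes HSPB1 (1.09 ± 0.41), HSPH1 (1.64 ± 0.71, and 1.09 without high gain cow 2) and XBP1 (0.65 ± 0.25) and the glucocorticoid target FKBP5 (1.67 ± 0.72) had higher estimates in high gain cows. None of these differences passed: by limma 0 genes had an adjusted p under 0.05 (smallest 0.889), and 716 had an unadjusted p under 0.05 where chance gives 709.9.

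At biopsy 1, 7 lists were higher and 1 lower in high gain cows by camera with the preset correlation. Heat shock (median 0.55), slow fibre (1.21), citric acid cycle (0.58), myogenic (0.54), glycolysis (0.46), respiratory chain (0.41) and proteasome (0.20) were higher, and fatty acid synthesis was lower (-0.46). With an estimated correlation none passed, and the adjusted p was 0.773 for heat shock and myogenic and 0.830 for the rest. Adjusted over the list alone 2 myogenic genes and 1 heat shock gene were higher, and none passed in the other 6 lists. Without the 2 cows with an array apart, among them the low gain cow with little ACTA1, the medians were 0.16 for slow fibre, -0.27 for citric acid cycle, -0.28 for respiratory chain and -0.28 for glycolysis, but 0.67 for heat shock and 0.19 for myogenic. The proteasome (0.016) and fatty acid synthesis (-0.19) lost their calls there, with adjusted p of 0.666 and 0.324, as did slow fibre (0.664) and glycolysis (0.101). Citric acid cycle and respiratory chain passed as lower (adjusted p = 0.00626 and 0.000142). Extracellular matrix (median 0.48, adjusted p = 0.00025), endothelial (0.20, adjusted p = 0.00025) and smooth muscle markers (0.33, adjusted p = 0.0460) passed as higher. None of these passed with an estimated correlation, where the smallest adjusted p of any list was 0.677. Since the 2 cows were chosen after their scores were seen, the calls without them do not test a class difference. Heat shock scores were 0.76 and 1.35 in high gain cows 1 and 2 and -0.20 to 0.24 in the other high gain cows. The slow fibre gene CSRP3 was 2.80 ± 1.34 higher in high gain cows, 1.68 without low gain cow 4 and 1.10 with array weights, and did not pass.

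At biopsy 2, during free feeding, TPPP2 (0.64 ± 0.14), RHBDD2 (0.37 ± 0.09) and the adenylate cyclase ADCY4 (0.38 ± 0.09) had the smallest unadjusted p values among genes higher in high gain cows, and FAM107B (-0.44 ± 0.09), the small GTPase RAP1B (-0.58 ± 0.15) and CSRNP1 (-0.48 ± 0.13) among those lower. Immediate early genes JUNB (-0.75 ± 0.29) and FOSB (-1.20 ± 0.47), HSPH1 (-0.59 ± 0.24), CEBPD (-0.77 ± 0.30) and NR1D1 (-0.80 ± 0.33) had lower estimates in high gain cows. SCD (-1.06 ± 0.76) and FASN (-1.44 ± 1.68) varied widely between cows. FASN was -3.31 without the 2 cows with an array apart, -0.69 with adipocyte markers as a covariate, -2.89 without high gain cow 4, -2.18 without low gain cow 5, -0.74 without low gain cow 2, -0.81 without low gain cow 6, -0.87 without high gain cow 1 and -0.90 without high gain cow 5, and SCD was -0.65 without high gain cow 5 and -1.68 without the 2 cows. By limma 0 genes passed (smallest adjusted p = 1), and 334 had an unadjusted p under 0.05 where chance gives 709.9.

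At biopsy 2, 3 lists were lower in high gain cows by camera with the preset correlation: immediate early (median -0.56), heat shock (-0.13) and respiratory chain (-0.20). With an estimated correlation the adjusted p was 0.342, 0.342 and 0.985. Without the 2 cows with an array apart the medians were -0.41 and -0.13, and that of respiratory chain turned to 0.07 and lost its call (adjusted p = 0.118). Adjusted over the list alone 0 members passed. The count of lists was 9 without high gain cow 4, 6 without low gain cow 5 and 10 without the 2 cows with an array apart; in the last case fatty acid synthesis had a median of -1.68 and adipocyte markers of -1.02. Sterol synthesis (-0.30), matrix (-0.29), fibroblast (-0.25) and macrophage genes (-0.11) were then lower and slow fibre (0.50) and proteasome (0.14) higher. The estimated correlation again gave 0 lists. Here too the 2 cows were chosen after their scores were seen, so the calls without them do not test a class difference.

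Averaged over both biopsies of each cow, TPPP2 (0.75 ± 0.16), the survival factor BCL2L1 (0.53 ± 0.12), FKBP5 (1.34 ± 0.47), the transcription factor FOXO1 (0.70 ± 0.21) and MYOD1 (0.60 ± 0.17) had higher estimates in high gain cows. The lymphocyte receptor CD226 (-0.37 ± 0.06), RAB7B (-0.45 ± 0.09) and NR1D1 (-0.84 ± 0.21) had lower ones. By limma 0 genes passed (smallest adjusted p = 0.805), and 526 had an unadjusted p under 0.05 where chance gives 709.9.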

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

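The tests of the array apart and of the odorant receptor genes were chosen after the results were seen, and the regroupings of cows were planned. Within each group of 6, the array farthest from the rest was looked for in array quality, in 27 list scores and in the named genes; chance marks about 1 in 20, that is 5.4 of 108 list scores, where 23 were marked, and 21.2 of 424 gene values, where 54 were.

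Low gain array 4 at biopsy 1 and high gain array 4 at biopsy 2 held most of these. The median correlation of the low gain array with its group was 0.862, and this array lay apart in 19 named genes. Relative to the mean of its set its scores were -5.96 for slow fibre, -4.07 for citric acid cycle, -3.66 for glycolysis, -3.57 for respiratory chain, -3.56 for fast fibre, -1.86 for myogenic, -1.55 for proteasome, -1.50 for fatty acid oxidation and -1.22 for heat shock genes. Endothelial markers were at 1.79 and smooth muscle markers at 1.49.

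A weak hybridization is argued against by the adipocyte score of this array, 2.60 above the mean of its set, where the other 11 arrays had an SD of 0.676. Tissue other than muscle fibre in the biopsy may account for the array: for 3 of the 4 lists of adipocyte, fibroblast, endothelial and smooth muscle markers it had the highest of the 12 scores. Macrophage and leukocyte markers were at 0.55 and red blood cell markers at 0.07. A wrong label was not tested, and no biological explanation was tested. The feeding period and gain class do not set this array apart, since the other 5 low gain arrays of biopsy 1 share them and had slow fibre scores of -0.41 or higher.

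High gain array 4 at biopsy 2 had a median correlation of 0.942 and lay apart in 22 named genes. Its marked scores were 4.08 for adipocyte markers, 3.74 for fatty acid synthesis, 1.65 for extracellular matrix, 1.41 for fibroblast markers and 1.35 for sterol synthesis, and -0.94 for myogenic, -0.92 for respiratory chain, -0.81 for citric acid cycle and -0.22 for proteasome genes. Its slow fibre score, -2.19, was the lowest of the biopsy 2 arrays but was not marked. Other marked values were a median correlation of 0.966 for high gain array 2 at biopsy 1, a median log2 value of 7.85 for high gain array 5 at biopsy 2, and at biopsy 1 scores of -0.58 for glycolysis in high gain cow 1, 0.48 for red blood cell markers in high gain cow 6 and 0.51 for Schwann cell markers in high gain cow 4. Low gain arrays 3 and 4 at biopsy 2 lay apart in 3 named genes each. Low gain array 2 at biopsy 2 lay apart in 2. High gain arrays 3 and 6 at biopsy 2 and high gain arrays 2, 4 and 5 at biopsy 1 lay apart in 1 each.

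Between gain classes, 6 lists differed in their biopsy shift by camera with the preset correlation, with medians, high minus low gain, of -1.10 for slow fibre, -0.69 for heat shock, -0.57 for citric acid cycle, -0.56 for immediate early, -0.50 for respiratory chain and -0.40 for myogenic genes. With an estimated correlation all 6 calls were lost (adjusted p = 0.326 to 0.962), and without the 2 cows with an array apart slow fibre, citric acid cycle and respiratory chain turned to 0.34, 0.39 and 0.42. Of 100 groupings of the 12 cows into 6 and 6, 95 gave at least 6 lists (highest other 18), so chance is not excluded. For the lists by gain 96 groupings gave at least the 8 of biopsy 1 (highest other 17) and 96 at least the 3 of biopsy 2 (highest other 16). For the list shifted between biopsies 98 of 100 draws that swapped the arrays of random cows gave at least 1 list (highest other 18). Counts this far above the real ones may come from a structure of the samples that moves many genes of a list together, which the preset correlation does not cover. This was not tested.

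The 5414 genes that passed between biopsies are the pattern most open to a technical source. Chance is argued against for the count: swapping the arrays of random cows gave no other count above 0 in 100 draws against the real 5414, so 1 of 100 was as large. Any swap mixes the 2 processing sets, so a processing shift alone would give the same result. In high gain cows 1 of 32 swaps was as large as 2876 (highest other 0), and in low gain cows 1 of 32 as large as 2878 (highest other 24). Separate processing of the 2 sets fits the share of odorant receptor genes past the threshold, 46.5%, and could account for changes of the size those genes show. Most of those genes were dim (median level 6.36), so they do not bound a processing shift in brighter genes. For the larger changes the feeding period, processing and anything else that differed between the 2 occasions stay open, and the design does not separate them.

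For the counts of genes by gain and for the interaction the groupings cannot tell about chance, since the real counts were 0 and all 100 groupings gave at least as many by necessity. The highest other count was 0 at biopsy 1, 341 at biopsy 2, 8 over both biopsies and 14 for the interaction. At biopsy 2 this was the only other grouping with any gene, and what its cows share was not tested.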

How the results depend on the processing

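Leaving out the 2 cows with an array apart, the values as deposited, the odorant receptor limit and the adipocyte covariate were chosen after seeing the data. Of 142 named values, ADIPOQ and PLIN1, which did not pass, were the 2 that turned, with ranges of -1.26 to 0.075 and -0.98 to 0.26 when each cow was left out and the upper values without low gain cow 4. Of 81 named changes that passed, 69 passed under every alternative; of 3500 alternative values 76 lost and 17 gained the threshold. With the adipocyte covariate, which holds these genes, ADIPOQ (-1.42), PLIN1 (-0.99) and FABP4 (-1.98) passed as lower.

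The ordinary t statistic ended 9 calls, among them THRSP (adjusted p = 0.0552, the highest of its alternatives), PCK2, SLC25A1, SLC2A4, LPL and GBE1 in all cows. Leaving out a cow ended the call of LPL for 7 cows (1.01 to 1.25), GBE1 for 9 (0.58 to 0.76), SLC25A1 for 6 (1.35 to 1.68), SLC2A4 for 5 (1.29 to 1.44), DGAT1 for 4 (0.36 to 0.40) and PCK2 for 2 (2.15 and 2.36) in all cows. In high gain cows it ended the call of ACSS2 for 10 cows (1.87 to 3.50) and AQP7 for 3 (1.68 to 1.93), and in low gain cows of HSPB7 for 4 (2.10 to 3.32) and BDH1 for 5 (1.49 to 2.09). Array weights moved CSRP3 (1.10), MYOG (1.33), ANKRD1 (1.62), XIRP1 (1.53) and DBP (-0.33) at biopsy 1, FASN at biopsy 2 (-2.32) and FOS in the interaction (-1.53) by over 1.5 times, none past the threshold. The mean of a gene's features moved LDHA to -0.73, which passed. Signal over background limits dim genes, and the upper end of the scale limits bright ones.

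The count between biopsies in all cows was 3268 with the stricter filter on dim genes, which tests fewer genes, and 369 for changes beyond the odorant receptor limit. In high gain cows it was 4425 without a filter, 1664 with the stricter filter and 4450 with array weights, and in low gain cows 4537, 1519 and, with adipocyte markers as a covariate, 4599. Leaving out each cow gave 4609 to 5886 in all cows, 1753 to 3980 in high gain cows and 1956 to 2933 in low gain cows. The 3980 came without low gain cow 4 and the 2933 without high gain cow 4. The classes share a fit, so a cow also moves the count of the other class. The interaction had 1 gene with the ordinary t statistic. For changes other than the filter and the size limit the cause was not tested.

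Without the block that pairs a cow's arrays the counts were 5471, 3113, 3121 and 0 genes, and 1 and 6 lists, and the random block over 24 arrays gave 0 genes for each comparison of gain, so the block moved no count past 1.5 times. Among named changes LDHA lost its call without it (-1.31, adjusted p = 0.0546, the highest of its alternatives), and no other call changed. The correlation between classes was 0.783 without a filter and 0.785 with cyclic loess, and 0.710 to 0.763 with each cow left out.

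With an estimated correlation camera gave 0 lists in all 4 comparisons, and fry gave 0 for the 2 comparisons of gain and for the interaction. Between biopsies fry gave 1 list, antioxidant genes (adjusted p = 0.0316), and the synthesis list did not pass it (adjusted p = 0.0611). Cyclic loess gave 5 lists for gain at biopsy 1. Without both cows with an array apart the lists were 10 for gain at biopsy 2 and 14 for the interaction. Leaving out each cow gave 1 to 2 lists between biopsies (2 without high gain cow 3 or 6 or low gain cow 1 or 4), 7 to 9 for gain at biopsy 1, 3 to 9 at biopsy 2 and 5 to 10 for the interaction. The cause was not tested. Counts of genes by gain were 0 under every alternative run.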

Other observations

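The families and tests in this part were chosen after the gene table was seen. These values do not test whether the families stand apart, since they were picked for their change. Of 10 genes of SR splicing factors 7 fell and none rose (median -0.77), led by SRSF1 (-1.36 ± 0.21, SE, n = 12 cows), SRSF5 (-1.29 ± 0.25) and SRSF3 (-1.11 ± 0.11), each lower in 12 of 12 cows. Of 20 heterogeneous nuclear ribonucleoprotein genes 12 fell and 2 rose, with HNRNPA1 at -1.39 ± 0.21, HNRNPU at -1.16 ± 0.16 and HNRNPD at -1.01 ± 0.18. The medians stayed below 0 under all 4 scalings, at -0.59 and -0.31 with the values as deposited. Of 15 glutathione S-transferase genes 8 rose and 1 fell (median 0.55), with GSTM2 at 1.98 ± 0.14 and GSTK1 at 1.21 ± 0.26 in 12 of 12 cows. Medians were 0.09 for 63 cytosolic ribosomal protein genes, 0.14 for 76 mitochondrial ribosomal protein genes and 0.09 for 38 mitochondrial solute carriers.

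The fatty acid synthesis list was picked here because it alone of 27 lists passed camera with the preset correlation on these same arrays. That call was lost with an estimated correlation. The exact p that follows is not adjusted over the lists and gives no new support. The list's mean within-cow change was 1.47 ± 1.99 (SD, 12 cows; exact p = 0.0225 over 4096 swaps, two-sided), against 0.39 ± 2.04 for adipocyte markers (exact p = 0.530). The 2 changes followed each other across cows (Pearson 0.986, permutation p = 1e-05, the smallest these permutations give; Spearman 0.923, permutation p = 2e-05; 0.958 without the 2 cows farthest out). More adipocytes as the whole cause is argued against by the intercept: at no change of adipocyte markers the synthesis list was 1.09 ± 0.10 (SE) higher, 1.10 ± 0.13 without the cows with an array apart, and 1.65 ± 0.21 when set against ADIPOQ, PLIN1, FABP4 and CIDEC alone. A processing shift blind to what genes do stays open. The list's median lay at percentile 100 of 10000 random lists matched on mean level, but random lists lack the correlation of the list's members, and the slow fibre list, with no member past the threshold, lay at 99.8. Processing that acts on these probes through GC content was not tested and stays open. The feeding period and anything else that differed between the 2 biopsies stay open as well, since these and the processing set were the same contrast. This was the only relation between measures computed across cows.

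NR1D1, a clock repressor, averaged 0.84 lower in high gain cows over both biopsies, with -0.89 at biopsy 1 and -0.80 at biopsy 2. An exact permutation test over 924 groupings gave p = 0.00866 and, adjusted over 16 clock genes, 0.139, so the difference did not pass. The genes with opposite phase ARNTL (0.05) and NPAS2 (0.13) had exact permutation p of 0.799 and 0.169.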
